A study of Mus musculus with 4 samples.

How the data were processed

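RNA was measured in bone marrow-derived macrophages of wild-type (WT) mice and of mice lacking Hem1, the protein encoded by Nckap1l. Hem1 is the hematopoietic subunit of the WAVE regulatory complex, which activates Arp2/3-driven branching of actin. Per the labels' protocols, femoral marrow was cultured for 8 days in RPMI with 20% medium conditioned by L929 fibroblasts, a source of the macrophage growth factor CSF1, and 10% fetal calf serum. Per the series' design text, the 2 arrays of each genotype came from distinct mice, so that each p-value rests on 2 mice per genotype. Which part of Nckap1l was removed is not given in the sources used here. Per the same protocols, RNA was purified with a Qiagen kit, checked on a Bioanalyzer and labelled with biotin by the GeneChip Pico kit of Affymetrix.

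The deposited table holds log2 values for 4 arrays. The submitters' processing notes name RMA, a method that corrects background, normalizes and summarises the probes of a probe set, without a version or settings. The scale was read from the values, which run from 2.70 to 14.0 over all arrays. The arrays' distributions over all probe sets and controls differed. Their medians were 6.53 and 6.08 on the WT arrays and 6.63 and 6.11 on the Hem1 KO arrays (replicates 1 and 2). A quantile step across these arrays was therefore not visible. The deposited values were used as they stand, and centring and quantile normalization were tried as alternatives. The number of arrays limits the precision.

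Of the table's 29129 probe sets and controls, 19572 name 1 gene in the platform annotation, 0 name several, and 9557 name none there. The unnamed ones include 6546 negative controls and 377 other controls and were left out of the test. For 55 genes with more than 1 probe set, the one with the highest mean over all arrays was kept, which left 19505 genes. A mouse RefSeq gene table (GRCm38.p6) served only to find which genes neighbour Nckap1l. No coordinates are given, since the build behind the arrays is not given in the sources used here.

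Each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without an intensity trend or a filter on dim genes), with genotype as the only term, a two-sided test and Benjamini-Hochberg adjustment over all 19505 genes. A gene was called at an adjusted p under 0.05. The moderated test borrows its spread from all genes, with 11.2 prior degrees of freedom. An exact permutation test of 2 arrays against 2 cannot give a two-sided p under 0.333. Differences are Hem1 KO minus WT on the log2 scale, with limma's standard error (SE), and n is 2 arrays per genotype throughout.

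Background was set at the 95th percentile of 1448 olfactory, vomeronasal and taste receptor genes on each array, a level chosen after the data were examined. It was 5.88 and 5.51 on the WT arrays and 6.04 and 5.38 on the Hem1 KO arrays. Where a gene lay at or below it on both arrays of 1 genotype only, its fold is a bound, written "at least": the brighter group's mean against the mean of, per array, the higher of the background and the gene's own value.

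The comparison, its test, 35 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The lists cover the WAVE and Arp2/3 complexes, other actin factors, SRF-MRTF targets, integrins, adhesion, phagocytosis, macrophage identity, activation, metabolism, the neighbourhood of Nckap1l and markers of 9 other cell types. The results of 1 list are left out of the text and of the plot of lists, while counts over all lists include it. Each list was tested with limma's camera (preset correlation 0.01), adjusted over the 35 lists, and members were also adjusted over the list alone. Named are Nckap1l, the 12 genes per direction with the largest difference among those called with no overlap between the genotypes' arrays, and per list every called member up to 6, otherwise the 4 with the smallest p. Where a list had no called member, up to 2 with the smallest p are given as values. Predicted genes, small RNA genes and chemosensory receptors were left out of the 12, which passed over 2 called higher and 1 called lower. Other genes named were chosen after their values were seen, as stated beside them.

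The alternatives left out each array in turn, used the replicate number as a block, centred or quantile normalized the arrays, kept only the brighter genes, let the prior follow intensity, averaged the probe sets of a gene, tested all probe sets and controls, changed the threshold, or changed the list test. A fit that leaves an arm with 1 array assumes that it varies like the other group. Such fits gave the 12 named higher genes smaller adjusted p-values than the fit of all arrays. Calls kept or gained in them are therefore weak evidence.

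The fit was tested on simulated arrays of the 19505 genes, with 200 genes changed, in 10 runs with each of 2 ways of drawing the gene variances. With variances drawn from the fitted prior, a median of 76.5% of the genes changed by 2 log2 units and 4% of those changed by 1 were recovered, and unchanged genes made up a median of 4.04% of the calls (highest 9.71%). With each gene's shrunken variance used as it is, the first way tried, the medians were 98.5% and 22.5%, and unchanged genes made up 6.96% of the calls (highest 14.1%), above the nominal level. The draw from the prior was added after that excess was seen. Of 200 unshifted lists of 20 independent genes, camera put a median of 2.25% under an unadjusted p of 0.05. The simulation has no correlation between genes.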

Results

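Macrophages grown from the bone marrow of 2 WT and 2 Hem1 KO mice were profiled on 1 array each. In the comparisons below, WT and Hem1 KO macrophages stand for these cultures. Which cells in them held a transcript was not tested. Between 12587 and 13071 of the 19505 genes lay above background on an array. The WT arrays correlated with each other at r = 0.986 across genes and the Hem1 KO arrays at 0.980, and arrays of different genotype at 0.966 to 0.977 (genes are not independent replicates). Hem1 KO replicate 1 had a narrower spread of values than the other arrays, with an SD of 2.00 against 2.15 on each of them. The Y-linked genes Eif2s3y, Kdm5d and Uty lay below background on all 4 arrays, with values of 3.53 to 4.18, and therefore showed no difference in sex between the arrays.

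The series compares gene expression with and without Hem1. Nckap1l, which encodes Hem1, read 11.37 and 11.11 on the WT arrays and 10.04 and 9.62 on the Hem1 KO arrays. It was 2.66-fold lower in the Hem1 KO macrophages (log2 difference -1.41, SE 0.32, adjusted p = 0.0467 by limma) and stayed well above background in them. Probes outside a deleted part would check nothing about the labels, and which part was deleted is not given in the sources used here. The call ended without WT replicate 1 (-1.28, adjusted p = 0.381), without WT replicate 2 (-1.54, adjusted p = 0.128) and without Hem1 KO replicate 2 (-1.20, adjusted p = 0.0874).

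Of the 10 measured genes of the WAVE regulatory complex, Nckap1l was the only one that passed the threshold over all genes, and 1 was higher and 2 were lower when adjusted over the list alone. These were Nckap1, the counterpart of Nckap1l in non-hematopoietic cells (at least 2.02-fold higher, at or below background on both WT arrays, adjusted p = 0.112 over all genes), and, besides Nckap1l, the complex subunit Cyfip2 (-1.07, SE 0.31, adjusted p = 0.182); both were chosen for naming after their values were seen. The stromal cell markers rose beside Nckap1, with a median of 1.85. Nckap1 passed the threshold over all genes without WT replicate 1 and without Hem1 KO replicate 2, and not without either of the other arrays. Over its alternatives its log2 difference of 1.74 ran from 0.95 to 2.53. The WAVE list as a whole did not move against the other genes (median -0.20, camera adjusted p = 0.182). Among 29 measured genes next to Nckap1l in the RefSeq order, limma called 0, with 1 at an unadjusted p under 0.05, against 1.61% of the other genes (two-sided Fisher's exact p = 1). At that share few calls were to be expected among 29 genes, so 0 calls says little about an effect on the neighbours. They ran from position -25 to 4 relative to Nckap1l, and some, such as Gtsf1 and Glycam1, lay at background on all arrays. The shorter list of 12 neighbours fixed beforehand had 0 called, 0 at an unadjusted p under 0.05 and a median of -0.03 (camera adjusted p = 0.605). Its members with the smallest p were Pde1b (-0.37) and Calcoco1 (-0.34).

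Most genes that differed were higher in the Hem1 KO cultures. They included Mcpt8, a basophil granule protease (18.9-fold, log2 difference 4.24, SE 0.35), the insulin receptor substrate Irs1 (at least 15.6-fold) and the lysophospholipase Gdpd3 (16.4-fold, SE 0.32). Several encode matrix and bone proteins: the proteoglycan osteoglycin, Ogn (14.6-fold), bone sialoprotein, Ibsp (at least 8.61-fold), matrix Gla protein, Mgp (8.77-fold), and the integrin ligand nephronectin, Npnt (8.28-fold). Others act in insulin-like growth factor signalling: the binding protein Igfbp5 (9.92-fold), Pappa, a protease that cleaves such binding proteins (9.06-fold), and the receptor adaptor Grb10 (8.78-fold). The vasodilator peptide gene Adm was 14.4-fold higher and the calcineurin regulator Rcan2 at least 5.90-fold. The log2 difference of Adm, 3.85, was 2.94 without WT replicate 2 and 4.77 without WT replicate 1. Mcpt8 and Adm were above background on 1 of 2 WT arrays. The stromal cell markers were higher beside these genes, with a median difference of 1.85.

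In all, limma called 288 genes higher in the Hem1 KO macrophages, all by 2-fold or more and 158 by 4-fold or more in the fitted values, and 66 of them lay at or below background on both WT arrays. At an unadjusted p under 0.05, 709 were higher. Higher genes made up 91.7% of the 314 calls. Over all genes, 25.8% had no overlap between the genotypes' arrays, against 33.3% by chance. The 12 named genes stayed higher when any single array was left out. Their smallest log2 difference was then 2.52, for Grb10 without WT replicate 2. Whether they stay called is little tested by such fits, which gave them smaller adjusted p-values than all 4 arrays did. The count of genes called higher varied with the array left out.

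The genes lower in the Hem1 KO macrophages were led by Dcstamp, a membrane protein needed for the fusion of macrophages and osteoclasts. It read 10.36 and 10.22 in WT and 5.87 and 5.08 in Hem1 KO macrophages, at least 23.8-fold lower (adjusted p = 5.66e-05). Atp6v0d2, a proton pump subunit that also takes part in that fusion, was 5.38-fold lower (-2.43, SE 0.46). The collagenase gene Mmp8 was 4.62-fold lower (-2.21, SE 0.37), the transcription factor gene Egr2 4.42-fold (-2.14, SE 0.40) and Slamf8, a receptor of the SLAM family, 6.06-fold (-2.60, SE 0.41). Also lower were Mamdc2 (8.68-fold), Trim30d (7.28-fold), the serpin gene Serpinb9b (5.37-fold), Efr3b (4.79-fold), the coagulation factor gene F7 (at least 2.69-fold), the adenylate kinase gene Ak8 (4.04-fold) and neuropeptide Y, Npy (3.99-fold). Trim30d and Efr3b were above background on 1 of 2 Hem1 KO arrays.

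In all, limma called 26 genes lower, all by 2-fold or more and 12 by 4-fold or more in the fitted values, 3 of them at or below background on both Hem1 KO arrays, with 306 at an unadjusted p under 0.05. The count was 54 without WT replicate 2, 101 without Hem1 KO replicate 1, 53 without Hem1 KO replicate 2, and 16 after quantile normalization, which ended the calls of Trim30d, Atp6v0d2, F7, Egr2, Ak8 and Npy. The calls of F7 (adjusted p = 0.337), Egr2 (-1.69) and Ak8 (-1.62) ended without WT replicate 2 and that of Npy (-1.61) without WT replicate 1, and Trim30d stood at -1.77 without Hem1 KO replicate 1.

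**Figure D1:**
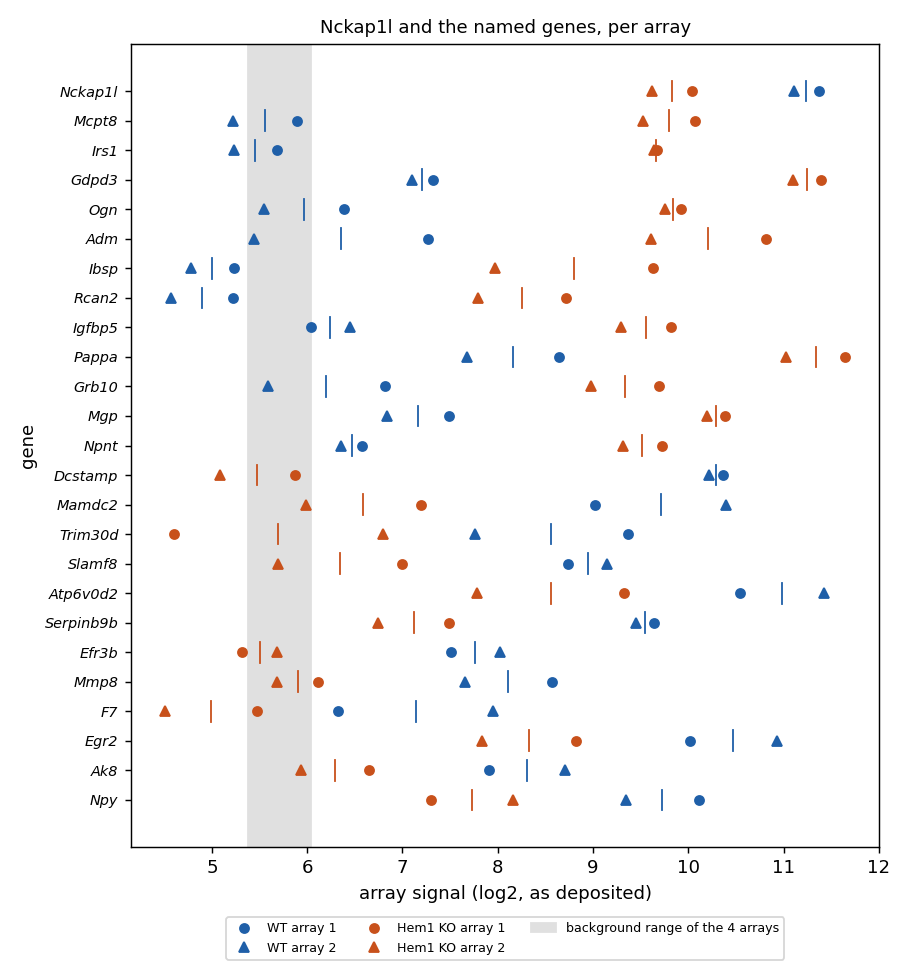
Log2 array signal as deposited (horizontal axis) of Nckap1l and the 12 named genes per direction (vertical axis), with WT arrays in blue, Hem1 KO arrays in orange, circles for replicate 1, triangles for replicate 2, a vertical line at each mean and grey for the range of the arrays' backgrounds. Dcstamp reads 10.36 and 10.22 on the WT arrays and 5.87 and 5.08 on the Hem1 KO arrays.

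Several stromal markers were higher in the Hem1 KO cultures. Of 10 measured stromal cell markers, 6 were higher and 0 lower, and 7 were higher adjusted over the list alone. They include the collagens Col1a1 (3.92-fold), Col1a2 (3.83-fold) and Col3a1 (2.96-fold), the growth factor receptor Pdgfrb (5.14-fold), the chemokine Cxcl12 (4.17-fold) and smooth muscle actin, Acta2 (3.37-fold). Their median difference was 1.85 (camera adjusted p = 4.74e-17, and adjusted p = 0.854 with an estimated correlation). Col1a1 was well above background in the WT cultures too, at 9.04 and 8.82. Without WT replicate 2 the calls of Acta2 (adjusted p = 0.165), Col1a2 (1.58) and Col3a1 (1.17) ended.

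Targets of SRF and its coactivators MRTF, which respond to actin assembly, also lay above the other genes by camera: 9 of 24 measured were higher, 0 were lower, and 13 were higher adjusted over the list alone. The leading members were the calponins Cnn1 (7.48-fold, log2 difference 2.90, SE 0.33) and Cnn3 (5.87-fold, 2.55, SE 0.31), the LIM protein Fhl2 (6.98-fold, 2.80, SE 0.33) and tropomyosin Tpm2 (6.45-fold, 2.69, SE 0.34), all genes of contractile cells. The median was 1.08 (camera adjusted p = 2.94e-23, and adjusted p = 0.854 with an estimated correlation). The list shares Acta2 with the stromal markers, whose median was 1.85.

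Among 21 measured matrix and protease genes, 5 were higher and 2 lower, and 9 were higher and 2 lower adjusted over the list alone. Gelatinase Mmp2 (5.97-fold) and the protease inhibitors Timp3 (5.32-fold) and Timp1 (4.53-fold) were higher, and Mmp8 was lower. The median was 0.67 (camera adjusted p = 0.00127, and adjusted p = 0.854 with an estimated correlation), beside 1.85 for the stromal markers. Without WT replicate 2 the median was -0.04 while camera still placed the list upward (adjusted p = 7.83e-05), and without Hem1 KO replicate 1 the median was 0.41.

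Few regulators of actin passed the threshold. Cortactin, Cttn, an Arp2/3 cofactor, was higher (3.09-fold, 1.63, SE 0.35), 1 of 20 measured Arp2/3 genes, as many as adjusted over the list alone (median -0.12, camera adjusted p = 0.277). Of 30 formins and actin turnover factors, 2 were higher, also adjusted over the list alone: the bundling protein fascin, Fscn1 (8.11-fold, 3.02, SE 0.45, above background on 1 of 2 WT arrays), and Enah (3.31-fold, 1.73, SE 0.34), which speeds filament growth (median 0.02, camera adjusted p = 0.605). Of 25 adhesion and podosome genes, 3 were higher and 4 adjusted over the list alone: the integrin-linked Parva (5.33-fold), talin Tln2 (3.60-fold) and the membrane protease Mmp14 (3.21-fold). That list had a median of -0.20, a mean of 0.17 and an upward camera statistic (adjusted p = 0.604). The stromal markers rose beside these genes, with a median of 1.85. The call of Cttn ended without WT replicate 1 (1.61), WT replicate 2 (1.64) or Hem1 KO replicate 1 (1.21), and those of Enah (1.39) and Mmp14 (1.23) ended without WT replicate 2. Without Hem1 KO replicate 1, camera placed upward the formin list (median 0.04, adjusted p = 0.00796) and the adhesion list (median -0.14, adjusted p = 0.0256).

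Limma called 0 of 16 integrin subunits, with 1 higher and 1 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone. Itgb2, the shared subunit of leukocyte integrins, read -0.97 (SE 0.37) and passed without Hem1 KO replicate 2 (-1.33). Itgb2 read -0.61 without Hem1 KO replicate 1 and -0.62 without WT replicate 2. Itgad was above background on 1 of 4 arrays. The list's median was 0.01 and its mean -0.07 (camera adjusted p = 0.492).

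Targets of the lipid sensors LXR and PPAR and lysosomal genes lay below the other genes by camera, with few members called. Of 14 measured LXR and PPAR targets, 2 were lower and 0 higher, and 5 were lower adjusted over the list alone: the sterol receptor LXR alpha, Nr1h3 (3.49-fold, -1.80, SE 0.34), and lipoprotein lipase, Lpl (2.83-fold, SE 0.33), passed over all genes. The median was -0.71 (camera adjusted p = 3.33e-08, and adjusted p = 0.854 with an estimated correlation). Of 22 lysosomal genes, 21 lay under 0, with a median of -0.33 (camera adjusted p = 4.24e-07, and adjusted p = 0.854 with an estimated correlation), and Atp6v0d2 alone passed, over all genes and over the list alone. The call of Lpl ended without WT replicate 2 (-1.27) and after quantile normalization (-1.41), which also ended that of Atp6v0d2 (adjusted p = 0.133). The stromal markers moved the other way, with a median of 1.85. Macrophage identity and phagocytosis genes fell about as much as the lysosomal ones, with medians of -0.26 and -0.32.

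Of 11 osteoclast markers, 3 were lower and 0 higher, and 4 were lower adjusted over the list alone. Dcstamp, Atp6v0d2 and the gelatinase Mmp9 (3.37-fold, -1.75, SE 0.33) were the called ones. The median was -0.11 and the mean -0.88 (camera adjusted p = 1.30e-05, and adjusted p = 0.854 with an estimated correlation), and the other members lay on both sides of 0. The call of Mmp9 ended without WT replicate 2 (-1.45) and after quantile normalization (-1.82), which also ended that of Atp6v0d2 (adjusted p = 0.133), and without Hem1 KO replicate 2 the list's median was 0.04 with camera still downward (adjusted p = 7.59e-06). Without WT replicate 2 or Hem1 KO replicate 1 the median was -0.37 or -0.22. The stromal markers stood at a median of 1.85.

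Among macrophage identity genes, limma called 0 of 18, with 2 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone, and 15 lay under 0. Gpnmb read -0.89 (SE 0.31) and the cytokine receptor chain Csf2rb -0.84 (SE 0.35). The median was -0.26 (camera adjusted p = 0.00471, and adjusted p = 0.854 with an estimated correlation). Of 28 phagocytic receptors and signalling genes, 0 were called, with 4 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone. The immunoglobulin receptor Fcgr4 read -1.17 (SE 0.36) and the scavenger receptor Cd36 -0.89 (SE 0.31), with a list median of -0.32 (camera adjusted p = 0.000865, and adjusted p = 0.854 with an estimated correlation). Without Hem1 KO replicate 1 both list calls ended (adjusted p = 0.369 for identity genes and 0.0654 for phagocytosis), as they did after quantile normalization (0.221 and 0.0698). The identity median was -0.05 without WT replicate 1 and -0.45 without WT replicate 2, and the phagocytosis median was -0.15 without Hem1 KO replicate 2. Fcgr4 passed without Hem1 KO replicate 1 (-1.46), while without WT replicate 1 Fcgr4 read -0.77 and Csf2rb -0.48. The stromal markers moved the other way from both lists, with a median of 1.85.

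Type I interferon response genes lay below the other genes by camera, and this call rested on 1 array. Limma called 0 of 31, with 7 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone, while 30 lay under 0 with a median of -0.68 (camera adjusted p = 5.66e-13, and adjusted p = 0.854 with an estimated correlation). Cmpk2 read 8.98 and 7.23 on the WT arrays and 6.30 and 6.64 on the Hem1 KO arrays (-1.63, SE 0.46), and Oasl2 read -1.03 (SE 0.35). Without WT replicate 1 the median was 0.05 and the call ended (adjusted p = 0.101), and without WT replicate 2 the median was -1.32. Cmpk2 passed without WT replicate 2 (-2.51), Hem1 KO replicate 1 (-1.47) or Hem1 KO replicate 2 (-1.80). Without WT replicate 1, Cmpk2 read -0.76 and Oasl2 -0.58.

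Camera placed none of the other activation lists apart on all arrays, but single arrays decided this for 5 of them, and Egr2 was their only called member. Of 11 interferon gamma response genes, limma called 0, with 1 lower at an unadjusted p under 0.05 (median -0.27, camera adjusted p = 0.133); Igtp read -0.86 and Cd274 -1.05. Of 29 inflammatory cytokines and NF-kB targets, 0 were called, with 1 higher at an unadjusted p under 0.05 (median -0.03, mean 0.01, camera adjusted p = 0.934), and those with the smallest p, Il12a and Il6, lay below background on all arrays. Of 18 alternative activation genes, Egr2 was lower (median 0.25, camera adjusted p = 0.228). Egr2 was also the only 1 of 18 immediate early genes to pass (median -0.20, camera adjusted p = 0.0719), and in both lists it alone passed over the list. The 9 class II presentation genes had 0 called and 0 at an unadjusted p under 0.05 by limma (median -0.23, camera adjusted p = 0.305), with H2-Ob at 0.52 and H2-Aa at -0.91. Of 17 chemoattractant receptors, 0 were called, with 2 lower at an unadjusted p under 0.05 (median -0.29, camera adjusted p = 0.125); Ccr1 read -0.84 and C5ar1 -0.78. Of 5 NADPH oxidase subunits, 0 were called, with 1 lower at an unadjusted p under 0.05 (median -0.28, camera adjusted p = 0.0696); Ncf4 read -0.73 and Cybb -0.35. In the lists with 0 called here, 0 passed adjusted over the list alone. Without WT replicate 2 camera placed downward the lists of interferon gamma (median -0.86), inflammation (-0.45), class II (-0.69), immediate early genes (-0.47) and chemoattractant receptors (-0.46). Without Hem1 KO replicate 1 it did so for interferon gamma (-0.38), inflammation (-0.44), class II (-0.41) and immediate early genes (-0.52), while the inflammatory list passed upward without WT replicate 1 (0.69) or Hem1 KO replicate 2 (0.58). H2-Aa read 0.05 without WT replicate 1 and 0.53 without Hem1 KO replicate 2, and passed without WT replicate 2 (-1.87) or Hem1 KO replicate 1 (-2.35). Cd274 read 0.05 without Hem1 KO replicate 2 and passed without the same arrays as H2-Aa (-1.74 and -2.14), and Igtp read -0.41 without WT replicate 1.

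Of 20 ATF4 targets, which serve amino acid supply under stress, limma called 0, with 4 higher at an unadjusted p under 0.05 and 4 adjusted over the list alone, and 17 lay above 0 (median 0.36, camera adjusted p = 3.86e-05, and adjusted p = 0.854 with an estimated correlation). The amino acid transporter Slc7a5 read 1.43 (SE 0.42) and the serine synthesis enzyme Phgdh 1.28 (SE 0.36); the stromal markers stood at 1.85. Adm was the only 1 of 24 glycolysis and hypoxia genes to pass, also adjusted over the list alone (median 0.07, camera adjusted p = 0.277). Of 12 NRF2 targets, 0 were called by limma, with 1 higher at an unadjusted p under 0.05 and 1 adjusted over the list alone (median -0.01, mean 0.01, camera adjusted p = 0.846), and Me1 read 1.15 and Srxn1 -0.64. Of 16 cholesterol synthesis genes, 0 were called, 0 at an unadjusted p under 0.05 and 0 over the list alone (median -0.05, camera adjusted p = 0.277), with Dhcr7 at -0.53 and Msmo1 at -0.38. Of 29 cell cycle genes, 0 were called, with 1 lower at an unadjusted p under 0.05 and 0 over the list alone (median 0.09, camera adjusted p = 0.432); Pcna read -0.82 and Ccne1 0.60. Without single arrays the ATF4 median ran from 0.23 to 0.64, cholesterol genes passed downward without WT replicate 1 (-0.24) or Hem1 KO replicate 2 (-0.25), and cell cycle genes passed upward without Hem1 KO replicate 1 (0.88) and downward without Hem1 KO replicate 2 (-0.58). Slc7a5 read 0.77 without WT replicate 2 and passed without WT replicate 1 (2.09) or Hem1 KO replicate 2 (1.72), and without the latter Phgdh (1.61) and Me1 (1.36) passed too. Glycolysis and hypoxia genes passed upward without Hem1 KO replicate 2 (0.27) and after quantile normalization (0.13).

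Few markers of other blood lineages were called. Among 11 monocyte and immature myeloid markers, Plac8 was higher (5.45-fold, 2.45, SE 0.36, above background on 1 of 2 WT arrays), also adjusted over the list alone (median 0.18, camera adjusted p = 0.0174, and adjusted p = 0.904 with an estimated correlation), beside 1.85 for the stromal markers. That list's call ended without WT replicate 2 (median -0.05, adjusted p = 0.611), after quantile normalization (adjusted p = 0.124) and among genes above background (median 0.71, adjusted p = 0.0518), and the median was 0.91 without WT replicate 1, 0.01 without Hem1 KO replicate 1 and 0.52 without Hem1 KO replicate 2. Mcpt8 was the only 1 of 11 mast cell and basophil markers to pass (median 0.04, camera adjusted p = 0.182), Mmp8 the only 1 of 14 neutrophil markers (median -0.10, camera adjusted p = 0.233), and the interleukin 7 receptor Il7r (2.96-fold lower, -1.56, SE 0.34) the only 1 of 12 T and NK cell markers (median -0.03, camera adjusted p = 0.401), each also adjusted over the list alone. The call of Il7r ended without WT replicate 1 (-1.63), WT replicate 2 (adjusted p = 0.163) or Hem1 KO replicate 2 (-1.18), and after quantile normalization (-1.45). Limma called 0 of 9 B cell markers, with 1 higher at an unadjusted p under 0.05 and over the list alone (median -0.04, mean 0.01, camera adjusted p = 0.633); Ebf1, which is also expressed in stromal cells, read 1.76 (SE 0.42), and Pax5, at or below background on both Hem1 KO arrays, was at least 1.12-fold lower without passing. It called 0 of 10 dendritic cell markers (median -0.09, camera adjusted p = 0.604; Batf3 -0.29, Siglech at background on all arrays) and 0 of 9 erythroid and megakaryocyte markers (median 0.09, camera adjusted p = 0.944; Car1 at background on all arrays, Epor -0.22), with 0 at an unadjusted p under 0.05 and 0 over the list alone in both. Without Hem1 KO replicate 1 camera placed downward the neutrophil (median -0.60) and T and NK cell markers (-0.42), and without WT replicate 2 the neutrophil markers (-0.38). Without each array in turn camera placed the mast cell and basophil list upward, with medians of -0.21 to 0.20. On all arrays Mcpt8 differed by 4.24, while the 10 other markers had a median of 0.01 and 7 of them lay at background. Ebf1 read 1.11 without Hem1 KO replicate 1 and passed without WT replicate 1 (2.06) or Hem1 KO replicate 2 (2.40), and Epor read 0.26 without Hem1 KO replicate 2.

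By camera, 5 of the 35 lists lay above and 7 below the other genes. With a correlation estimated from the arrays, 0 of the 12 calls held, with 0 at an unadjusted p under 0.05, and fry called 0, with 2 at an unadjusted p under 0.05. With 4 arrays, camera in that setting could hardly call a list, so it does not decide whether the calls hold. For the SRF-MRTF and stromal lists the estimated correlation was 0.56 and 0.72, above the preset 0.01. Camera on ranks ended the calls of the matrix (adjusted p = 0.215), osteoclast (0.125) and monocyte lists (0.109). It added the Arp2/3 (0.0463), alternative activation (0.0440) and NADPH oxidase lists (0.0463).

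**Figure D2:**
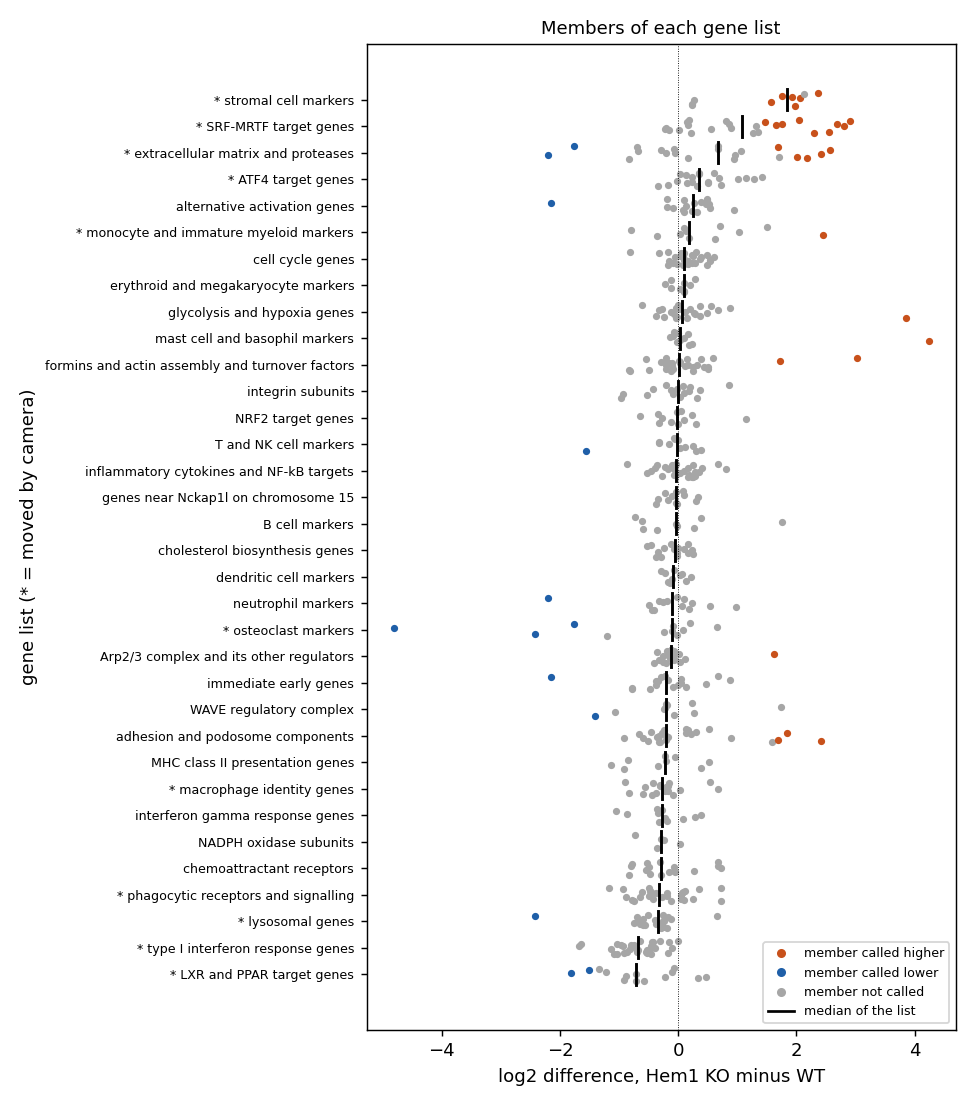
Log2 difference, Hem1 KO minus WT (horizontal axis), of each measured member of the gene lists, 1 of the 35 left out, (vertical axis), in orange where called higher, blue where called lower and grey otherwise, with a black line at the list's median and an asterisk where camera with the preset correlation placed the list apart. The stromal markers have the highest median, 1.85, and the LXR and PPAR targets the lowest, -0.71.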

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

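Quantile normalization together with the replicate block, and the restriction to genes above background, were chosen after seeing the data; the other settings were planned. With 2 arrays per genotype, leaving out single arrays gave 185 to 545 genes higher, 26 to 101 lower, 14 to 19 lists moved and -1.62 to -1.20 for Nckap1l. Keeping the brighter genes gave 136 higher and 4 lower, and keeping those above background 183 and 11; Nckap1l stayed at -1.41 but lost its call in both (adjusted p = 0.0761 and 0.0798, from 6.61e-10 to 0.381 over its alternatives). Centring gave 70 lower and shifted the median of all genes by -0.10, which put list medians between 0 and 0.10 under 0; quantile normalization gave 16 lower, and the intensity trend 205 lower and 19 lists. Calling genes in Hem1 KO macrophages at an unadjusted p under 0.05 and at least 2-fold gave 499 genes higher and 95 genes lower. Camera with an estimated correlation and fry moved 0 lists. The causes were not tested. The labels share replicate numbers between genotypes but state no pairing, and the mice differ; same-numbered arrays' deviations correlated at 0.241 over all genes and 0.349 over those above background on all arrays, with 2 pairs. With the replicate block there were 620 higher and 199 lower, and with quantile normalization as well 439 and 69. Not passing as a whole, the inflammatory list passed downward without WT replicate 2 (-0.45) or Hem1 KO replicate 1 (-0.44), and upward without WT replicate 1 (0.69) or Hem1 KO replicate 2 (0.58). Ptgs2 passed downward at -1.71 without Hem1 KO replicate 1, and upward at 1.91 without Hem1 KO replicate 2. Cell cycle genes passed downward at -0.58 without Hem1 KO replicate 2, and upward at 0.88 without Hem1 KO replicate 1. Of 1182 alternative values of 100 named genes, 1024 stayed on the same side of the threshold, 22 of these with the opposite sign and no call either way, while 71 lost and 86 gained a call. Of 522 list values, 440 stayed on the same side, 40 of these with a median of the opposite sign, while 41 lost and 38 gained a call. Sex as a block was not run, as the Y-linked genes lay below background throughout.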

Other observations

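The tests of explanations and the count of splits were chosen only after the results were seen. Some programmes differed between arrays of the same genotype more than between genotypes. The inflammatory list was higher on replicate 1 than on replicate 2 in both genotypes after quantile normalization, by a median of 0.67 in WT and 0.58 in Hem1 KO macrophages, with 25 and 23 of 29 members higher. Il1b, the gene of interleukin 1 beta, read 11.81 and 8.38 on the WT arrays and 11.36 and 7.80 on the Hem1 KO arrays, Cxcl2, a chemokine that draws neutrophils, 9.95 and 6.75 against 9.15 and 6.77, and the class II gene H2-Eb1 11.72 and 8.80 against 10.97 and 7.28. Immediate early genes went the same way, by 0.42 and 0.73. The interferon list was higher on replicate 1 in WT, by 0.89, and lower on it in Hem1 KO macrophages, by -0.31 with 6 of 31 members higher; Irf7, a regulator of interferon genes, read 10.62 on WT replicate 1 and 7.18, 7.21 and 7.25 on the other arrays. Cell cycle genes split in the Hem1 KO macrophages: 0 of 29 were higher on replicate 1, with a median gap of -1.77 against -0.24 in WT, and the proliferation marker Mki67 read 9.49 and 11.29. These genes were chosen after their values were seen.

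Csf1, which encodes the growth factor that macrophages depend on, was higher in the Hem1 KO cultures (1.93, adjusted p = 0.0175 by limma), and its call ended without WT replicate 2 (1.43). The stromal markers rose beside Csf1, with a median of 1.85, and which cells hold its transcript was not tested. Gzmc, a granzyme gene related to Mcpt8, was at or below background on both WT arrays and at least 1.17-fold higher in the Hem1 KO macrophages. Both were chosen after their values were seen.

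Of the 3 ways to split the 4 arrays into 2 and 2, the genotypes gave 314 called genes and the highest of the others 1; only 1 split gave as many, and 3 splits are too few for a share under 0.05.

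The higher level of stromal and contractile genes was set against array scaling and against a larger share of stromal cells in the Hem1 KO cultures. Scaling as the whole cause is argued against, since 91.3% of the 288 genes stayed called after quantile normalization, with a median fitted difference of 2.04 against 2.06 before. More stromal cells stays open as a candidate explanation: a larger share would move their markers by 1 factor, and the 6 markers above background in both genotypes, from the list fixed beforehand, ran from 1.57 to 2.36 with an SD of 0.27 against a median SE of 0.34. That SE holds variation between mice, which the markers share in part (estimated correlation 0.72 for the list). An SD below it therefore does not show that 1 factor moved them. Of the 10 measured stromal markers, 7 lay above background in either genotype, and the others were not weighed. A further list of mesenchymal genes, written after the called genes had been seen and so not independent evidence, spread over 0.34 to 2.82 (20 genes above background in both genotypes, SD 0.87), from genes such as Postn, 9.75 and 9.95 in WT with a difference of 0.94, to Prrx1 at 2.82, so that the lists leave the explanation undecided. A change within the stromal cells, or expression of these genes by Hem1 KO macrophages themselves, stays open and was not tested.

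The genes lower in Hem1 KO macrophages were set against dilution by other cells and against scaling. Dilution as the whole cause is argued against, as it would lower macrophage genes alike. The 18 identity genes had a median difference of -0.26 (SD 0.40, and -0.45 to -0.05 without single arrays), against -1.96 for the called genes. The called genes were picked for their fall, with none above -1.39, which widened that gap. A smaller dilution stays open. Medians were -0.32 for phagocytosis, -0.33 for lysosomal and -0.28 for NADPH oxidase genes, beside 0.01 for integrin subunits. Scaling was left undecided by its test, as only 42.3% of the 26 genes stayed called after quantile normalization. The differences largely kept their size, and all 26 stayed beyond 1 log2 unit. Their median was -2.01 against -1.96 before (median SE 0.32 against 0.34). What ended the other calls was not determined. An effect of Hem1 loss on the macrophages is the biological explanation the design gives, and it remains a hypothesis.

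Mcpt8, one of the named higher genes, could mark basophils or mast cells, or carry signal from related genes, and neither was excluded. Of the 10 other markers of those cells, 7 lay at or below background on all arrays, and the 3 above it differed by at most 0.23, too few to decide. Of 14 other granzyme, chymase and Mcpt genes, 4 were above background on both Hem1 KO arrays, too few to decide on signal from related granzyme and mast cell protease genes as well. Which cells hold the transcript, stromal cells included, was not tested.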
